A study of Mus musculus with 4 samples.

How the data were processed

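Gene expression in cultured mouse SVEC endothelial cells was measured with 4 two-colour arrays. Per the labels, RNA was amplified, control and LPS-treated RNA were labelled with Cy3 and Cy5 and hybridised to Operon V1 long oligonucleotide arrays (the platform is named for 4 h only), and the second array of each time point had the dyes exchanged. Groups were LPS 4 h and LPS 24 h with 2 arrays each. The labels give no word on separate cultures, so both arrays of a time were taken as 1 RNA pair, and the spread between them is technical. The number of arrays limits the precision.

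The deposited table holds log2 ratios of the 2 dyes. The scale was settled from the values: they are centred on 0 with both signs, and 2 raised to the size of the value lies on steps of 0.01 for at least 99.96% of spots on each array, within 2 hundredths of a step. The median of each deposited column was 0. The scanner, the background correction and the normalization are not given in the sources used here, and the direction of the ratio is likely only. No intensities were in the table used, so faint spots could not be removed. Spots at a ratio of exactly 1 numbered 5307 and 2041 on the 4 h arrays and 3501 and 3267 on the 24 h arrays; they were kept, and taken as not measured in an alternative.

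Spots were named from the platform annotation that goes with the value table. Of 32448 spots, 24344 had 1 gene symbol, 98 had several and 8006 were not named, and only the first kind was used for genes. Entrez identifiers of 98.9% of named spots were found in the RefSeq gene table of GRCm38.p6, and 0 symbols were updated; no coordinates are given because that build is not the array's. The 12131 oligonucleotides stand for 11138 genes, of which 929 have more than 1. Spots of a gene were averaged, and the text says where the oligonucleotides of a gene named as past the 2-fold rule differed in sign at that time. Adjacent spots of the same oligonucleotide, 12092 pairs, correlated at 0.62 and 0.50 on the 4 h arrays and 0.41 and 0.26 on the 24 h arrays.

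Each array was centred on its median, the sign of the reversed arrays was turned, and the arrays of a time were averaged, so that a dye effect cancels. A gene counted as higher or lower when the mean was at least 1 on the log2 scale (2-fold) and each array was at least 1.5-fold the same way. The same rule with the reversed array turned back gave the number that dye effect and noise make. That number includes dye effect that cancels in the mean, so it may exceed the calls that noise alone makes. For the difference between times, the means had to differ by at least 1 and both arrays of a time had to lie beyond both of the other. The shared response was fitted with limma (lmFit and eBayes on the pair means, intercept only, 1 residual degree of freedom) with Benjamini-Hochberg adjustment at 0.05.

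Before the data were examined, 26 gene lists were fixed, among them markers of endothelial, lymphatic endothelial, leukocyte, mural and epithelial cells. For each, the median over measured genes and its percentile among 10000 random lists of the same size were computed. This describes the arrays and is no test, and lists could not be matched on intensity. The lists were counted as outside the random range below 2.5% or above 97.5%. After the first results had been seen, 7 more lists were drawn up: abundant transcripts outside translation, transcripts of unrelated tissues, further interferon-induced genes, iron and metallothionein genes, serum amyloid and secreted inhibitors, mitochondrial respiratory chain genes, and actin cytoskeleton and adhesion genes. Listed symbols that were not current were matched through synonyms. This matching was narrowed after first values had been seen, to remove matches of a current symbol to another gene; it lowered the 24 h median of the further interferon-induced genes and raised the 4 h median of the glycolysis list.

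Named genes follow a rule fixed before the data were examined. Per time it takes the 12 genes with the largest and the 8 with the smallest mean among those past the 2-fold rule, and up to 4 members of each fixed list with the largest size of mean at either time. It adds the 5 largest differences each way, those called by the shared fit, and always Tlr4, Cd14, Ly96, Myd88, Icam1, Vcam1, Sele and Selp where measured. Gbp2, Rsad2, Usp18, Ifit1, Ifit2, Ifit3, Ifi35, Igtp, Mx1, Stat2, Ifi203, Eif2ak2, Irf7, Isg15, Nfkbia, Cxcl10, Ccl5, Il6, Cdc6, Lum, Cd200, Ftl1 and all genes first named in the closing section were chosen after their values were seen.

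Alternatives were the values as deposited, scaling of arrays to one spread, quantile normalization, other fold thresholds, the mean alone, each spot by itself, leaving out each array in turn, limma on the 4 arrays taken as independent with and without a dye term, robust eBayes and an adjusted p threshold of 0.10. Added after seeing the data were exact zeros as not measured, centring on named genes and centring on abundant transcripts. The rules and fits were tested on simulated data made from the real arrays with 200 changed genes among 11138. The 2-fold rule recovered 50.5% of genes changed 2-fold and 91.5% of those changed 4-fold at 4 h, and 46.5% and 94.0% at 24 h. In the same runs, unchanged genes met the rule 230 and 257 times at 4 h and 174 and 193 times at 24 h. Noise and dye effect were drawn separately for each simulated array, so a shared dye effect did not cancel as it does in the real pairs. These shares and counts therefore need not hold for the real means. The shared fit recovered 67% of genes changed 4-fold and 99.5% of those changed 16-fold. There the change was the same at both times, and no gene differed between them beyond the spread within pairs. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.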

Results

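Mouse SVEC cells, an established line of endothelial cells, the cell type that lines vessels, were cultured with or without lipopolysaccharide (LPS), a cell wall component of Gram-negative bacteria that many cells sense through the receptor Tlr4. The title of the series puts the question as the response of these cells to LPS in culture. RNA of LPS-treated and control cells was amplified and hybridised together on long-oligonucleotide arrays with 2 dyes, after 4 h and after 24 h. Each time point had 2 arrays, with LPS in Cy5 on the first and in Cy3 on the second, which the labels call a dye reversal. Both arrays of a time point were therefore taken as 1 RNA pair measured again with the dyes exchanged, so each time point is 1 replicate. The SD given with a value is the spread between those 2 arrays and holds no variation between cultures. The dose was 50 ng/ml on the 3 arrays whose labels state it.

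The value table gave a log2 ratio for 32448 spots per array, with no intensities, and 24344 spots carried 1 gene symbol, for 11138 genes. The median of each deposited column was 0, and the SD over spots was 1.44 and 1.43 on the 4 h arrays and 0.978 and 1.07 on the 24 h arrays. As deposited, the arrays of a pair correlated below 0 over all spots, at r = -0.23 for 4 h and r = -0.042 for 24 h, so the values were read as dye over dye and the reversed array was turned in sign. The direction of every signed value here, LPS over control, is likely but not stated. It rests on the labels, which place LPS in Cy5 and in channel 2 of the unreversed arrays, and the opposite convention would turn every sign. After turning, the correlation across genes between the arrays of a pair was 0.48 at 4 h and 0.10 at 24 h; genes are not independent replicates. Between the times, the arrays with LPS in Cy5 correlated at 0.24 and those with LPS in Cy3 at 0.052. Arrays of opposite orientation correlated at 0.12 and -0.018.

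After 24 h with LPS, the interferon list had the highest median of the 26 fixed lists. Of its 34 measured members, 15 were at least 2-fold higher in LPS-treated cells and 0 were lower. The largest ratios belonged to Ifi47, an immunity-related GTPase, at a log2 ratio of 2.54 ± 1.13 (SD, 2 arrays), or 5.82-fold, and to Gbp2, a guanylate-binding protein, at 2.43 ± 0.53. Rsad2, the antiviral enzyme viperin, lay at 2.21 ± 0.66, and Usp18, a protease that removes ISG15 from proteins, at 2.17 ± 1.23. Outside that list, Timp1, an inhibitor of metalloproteinases, was 9.28-fold higher (3.21 ± 0.90), the metal-binding protein gene Mt2 8.87-fold (3.15 ± 0.55), and Saa3, an acute phase serum amyloid, 6.02-fold (2.59 ± 0.91).

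The other interferon genes past the 2-fold rule at 24 h were Ifit3 at 2.15, Irgm2 at 1.94, Ifit2 at 1.93, Ifi35 at 1.89, Igtp at 1.67, Ifih1 at 1.56, Mx1 at 1.55, Stat2 at 1.41, Ifi203 at 1.40, Eif2ak2 at 1.38 and Irf7 at 1.17. The rule itself demands that each array be at least 1.5-fold higher, so agreement in sign among these was fixed beforehand. Of all 34 members, 27 were above 0 on both arrays and 1 was below 0 on both. Isg15, at 0.63 ± 0.65, and Ifit1, at 0.71 ± 0.45, did not reach the rule. The list's median was 0.71, above all of 10000 random lists of its size, and it was 1.17 on the array with LPS in Cy5 and 0.71 on the reversed array. A list of 36 further interferon-induced genes, drawn up later, had a 24 h median of 0.064, at the 70.1st percentile of random lists, with 1 gene higher. Probes of Ifi203 cannot be assumed to be free of signal from closely related family members.

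**Figure D1:**
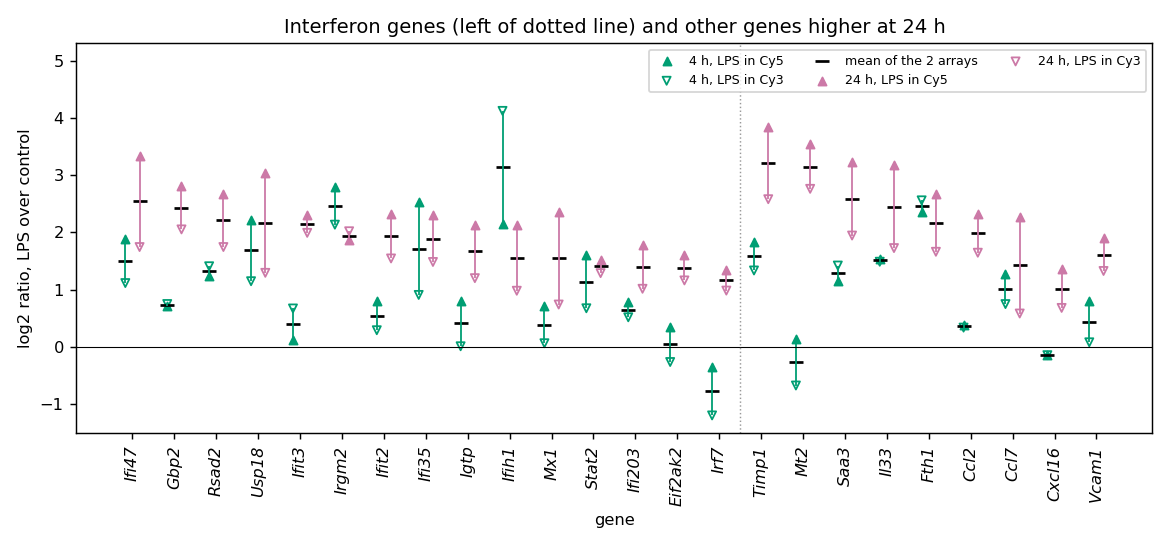
Log2 ratio of LPS over control (vertical axis) for 15 interferon genes past the 2-fold rule at 24 h and 9 other genes higher at that time (horizontal axis). Filled triangles are the array with LPS in Cy5, open triangles the reversed array, and black bars the mean of both; Gbp2 lies at 0.74 at 4 h and 2.43 at 24 h, while Irgm2 lies at 2.47 and 1.94.

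Among inflammatory genes at 24 h, 3 of 24 chemokines were higher and 0 lower. These were Ccl2, which attracts monocytes, at 1.98 ± 0.48, Ccl7 at 1.43 ± 1.19 and Cxcl16 at 1.02 ± 0.48. Cxcl10, at 0.20, and Ccl5, at 0.21, were not. Of 27 cytokines and growth factors, only Il33, an alarm cytokine of barrier and endothelial cells, met the rule, at 2.45 ± 1.03, while Il6 lay at -0.50 ± 1.14. The adhesion molecule Vcam1, which binds leukocytes, was the only 1 of 18 adhesion genes to be higher, at 1.61 ± 0.40; Sele lay at -0.28, Selp at 0.21, and Icam1 was not analysed here. In the NF-kB feedback list, 2 of 14 genes were higher, Tnip1 at 1.54 ± 0.29 and Ier3 at 1.40 ± 0.30, and Tnfaip3 lay at -1.04 ± 1.10. The inflammatory caspase genes Casp4, at 1.55 ± 0.97, and Casp1, at 1.21 ± 0.07, were the 2 of 18 cell death genes past the rule. The ferritin heavy chain gene Fth1 was higher by 2.17 ± 0.71, which with Mt2 made 2 of 17 oxidative stress and metal genes.

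The medians of the chemokine list (0.19, 95.9th percentile of random lists), the cytokine list (0.01), the adhesion list (0.06) and the NF-kB feedback list (0.08) lay inside the middle 95% of random lists. Of 26 lists, the interferon list and the ribosomal protein list (0.39, with Rplp1 and 1 other of 32 genes higher) lay outside it, where chance gives 1.3. None of the measured members of the antigen presentation, toll-like receptor, cell cycle, glycolysis, proteasome, immediate early, coagulation, prostaglandin, cholesterol or endoplasmic reticulum lists met the rule at 24 h. Single members were higher in the heat shock list (Hspd1, 1.25 ± 0.01) and the acute phase list (Saa3), and 2 of 32 in the extracellular matrix list (Timp1, and Sparc at 1.18 ± 0.19). Tlr4 itself lay at 1.02 ± 0.79, with arrays at 0.46 and 1.58, so it missed the demand on each array. Its partners Cd14, at 0.03, Ly96, at 0.00, and Myd88, at 0.18, were close to 0.

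Across all genes at 24 h, 187 of 11138 were at least 2-fold higher and 89 lower, 276 in all, against 189 when the same rule was applied to dye effect and noise. Of those 189, 55 were brighter in Cy5 and 134 in Cy3. Against this number the 89 lower genes as a set do not stand out. It holds dye effect that cancels in the mean, so it may overstate the calls made by noise alone. The highest named genes, beside those given, were Ttpal at 4.40 ± 0.77, Gpr165 at 3.18 ± 0.48, Tmem121b at 3.03 ± 3.01, Ccdc172 at 3.0 ± 1.24, Bcl7a at 2.87 ± 0.01, Flicr at 2.82 ± 0.73, Pgpep1l at 2.78 ± 2.40, Trafd1 at 2.72 ± 2.94 and Atp6v1c2 at 2.61 ± 0.86. All of these rest on 1 oligonucleotide per gene. The lowest were Ucn3 at -2.19 ± 0.48, the smooth muscle actin Actg2 at -2.16 ± 0.73, Ifna9 at -2.11 ± 1.92, Tmem80 at -2.06, Rgl3 at -2.02, Kcnip2 at -1.99, Hoxb3 at -1.94 and Sohlh2 at -1.92. With 1 RNA pair there is no test at this time. Without the unreversed array the split was 771 higher to 310 lower, and without the reversed array 502 to 818. Centring on the abundant transcripts gave 106 higher and 187 lower, and quantile normalization 411 and 148.

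After 4 h, genes of the protein synthesis machinery stood highest among the lists. Of 32 ribosomal protein genes, 25 were at least 2-fold higher and 0 lower, with a list median of 2.72; Rpl6 lay at 5.27 ± 1.24, Rps3 at 4.85 ± 2.05, Rps7 at 4.50 ± 2.29 and Rplp1 at 4.06 ± 1.29. Glycolysis genes followed, with 7 of 14 higher and 0 lower, among them Gapdh at 4.39 ± 1.0, Pkm at 3.61 ± 1.51 and Pgam1 at 3.52 ± 1.80. The interferon list also lay high, with 10 of 34 genes higher and 0 lower and a median of 0.39, though not all genes past the rule at 24 h were among them. Its largest ratios were Ifitm3 at 4.11 ± 2.03, the RNA sensor gene Ifih1 at 3.14 ± 1.39 and Irgm2 at 2.47 ± 0.47. The cytokine list was the only 1 of the 26 fixed lists below the random range, with a median of -0.37, where Tnfsf11 lay at -3.39 ± 0.17, Vegfa at -1.97 ± 0.69 and Inhba at -1.09 ± 0.25, and Il33 was higher at 1.51 ± 0.03. Transcripts of unrelated tissues, listed after the first results, also lay low, at -0.23 and the 0.2th percentile of random lists. The low cytokine median may thus be part of a shift with transcript abundance, which could not be settled without intensities.

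Cell cycle genes also stood high at 4 h. Of 29 measured, 11 were higher and 1, Cdc6, was lower at -1.36; the kinase gene Cdk4 lay at 3.48 ± 0.14 and the replication helicase genes Mcm2, Mcm4 and Mcm5 at 2.85, 2.70 and 2.25. In the extracellular matrix list, 12 of 32 were higher and Lum was lower at -1.40, with Sparc at 3.87 ± 1.73, Lox, which crosslinks collagen, at 3.42 ± 0.14 and Timp3 at 3.31 ± 1.21. The proteasome list had 8 of 22 higher, with Psmb1 at 3.27 ± 0.44 and Psma6 at 2.60 ± 0.73, and Psmb6 lower at -2.86 ± 1.70. The medians of these lists were 0.78, 0.63 and 0.54, each among the highest 2.5% of random lists. Of 26 lists, 7 lay outside the middle 95% at 4 h, where chance gives 1.3. Beside these groups, a list of abundant transcripts outside translation, drawn up after the first lists had been seen, had a median of 1.49, and transcripts of unrelated tissues a median of -0.23, at the 0.2th percentile of random lists. When each array was centred on the abundant transcripts, the median of the ribosomal list was 1.29 and those of the interferon, cell cycle, matrix, glycolysis and proteasome lists lay below 0, at -1.04, -0.65, -0.80, -0.11 and -0.89. This subtracts 1 constant per array, so any value between 0 and that constant turns in sign, and each list keeps its place among random lists. All list medians at 4 h are therefore relative to the array's median spot.

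In the NF-kB feedback list at 4 h, Ier3 (1.27 ± 0.54) and Nfkbiz (1.15 ± 0.19) were higher and Tnip1 (-1.81 ± 0.01) lower, with Nfkbia at 0.96 and Tnfaip3 at -0.91 short of the rule. Of 24 chemokines, Cxcl12 (1.30 ± 0.34) and Ccl7 (1.01 ± 0.37) were higher, while Ccl2 lay at 0.36 ± 0.03. The adhesion list had Itgb1 (3.77 ± 0.94) and F11r (2.18 ± 1.49) higher and Itga5 (-1.61 ± 0.35) and Cd200 (-1.22) lower; Vcam1 lay at 0.44, Sele at 0.28 and Selp at -0.11. All 4 of 20 antigen presentation genes past the rule were class I genes, H2-Q7 at 3.62, H2-K1 at 3.58, H2-D1 at 2.94 and H2-Q1 at 1.81, whose near-identical sequences a probe may not separate; the probes of H2-Q1 differed in sign. In the toll-like receptor list, Ikbkb was higher (1.26 ± 0.05) and the adaptor Myd88 lower (-1.05 ± 0.28), with Tlr4 at 0.76 ± 1.67, Cd14 at 0.81 ± 0.60 and Ly96 at 0.02. With centring on the abundant transcripts, Ier3, Nfkbiz, Ccl7, Cxcl12, Ikbkb and Saa3 turned in sign.

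Smaller groups at 4 h gave single values. Among heat shock genes, Hspa8 (2.53 ± 0.10), Dnaja1 (2.47 ± 0.47), Hspd1 (2.30 ± 0.04) and Cryab (1.91 ± 1.18) were the 4 of 12 that were higher. The immediate early genes Fos (1.87 ± 0.28) and Dusp2 (1.71 ± 0.76) were 2 of 21, each with 1 of its 2 oligonucleotides near 0 (0.0044 and 3.74 for Fos, 0.25 and 3.17 for Dusp2). Procr, the endothelial protein C receptor, lay at 2.21 ± 0.52, with Anxa2 at 1.61 and Gas6 at 1.31, while the thrombin receptor F2r was lower at -1.26 ± 0.28. Fth1 lay at 2.46 ± 0.14 and Sod1 at 1.14, and the light chain gene Ftl1 was lower at -1.10. Ptgds lay at 2.46 ± 1.80, Saa3 at 1.29 ± 0.19, C4b at -1.27 ± 0.29, Casp4 at 2.03 ± 1.06, Bad at 1.30, Gadd45b at -1.41 ± 1.02 and Canx at 1.05. With centring on the abundant transcripts, Gas6, Sod1, Bad, Saa3 and Canx turned in sign. No cholesterol synthesis gene among 9 met the rule; Sqle lay at 1.32 ± 1.22.

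Over all genes at 4 h, 973 were at least 2-fold higher and 643 lower, 1616 in all, against 204 from dye effect and noise. The highest, beside the ribosomal protein genes given above, were Il17rc at 6.58 ± 4.47, the histone gene H3f3b at 5.79 ± 1.94, Ppia at 5.76 ± 1.32, Clec12b at 5.74 ± 0.03, the poly(A)-binding protein gene Pabpc1 at 5.73 ± 1.43, Rgs19 at 5.25, Krtap4-6 at 5.20, Chmp5 at 5.14 ± 5.0, Atp5b at 5.06 and Ifi27l2a at 4.87 ± 0.75. Each of these rests on 1 oligonucleotide, with no other probe of the gene to check it. The lowest were Med26 at -5.02 ± 4.76, Ldhd at -5.01 ± 2.24, Ndel1 at -4.91, Tymp at -4.76, 4921513I03Rik at -4.70, 2900016B01Rik at -4.67, Mark2 at -4.54 and Asb3 at -4.53. Centring on the abundant transcripts changed the split from 973 higher and 643 lower to 197 and 6701. Without the unreversed array the split was 1376 to 1007, and without the reversed array 1476 to 996. With 1 RNA pair there is no test, and limma on the 4 arrays taken as independent samples called 134 higher and 76 lower, and 0 and 0 with a dye term (2373 genes at an unadjusted p under 0.05).

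**Figure D2:**
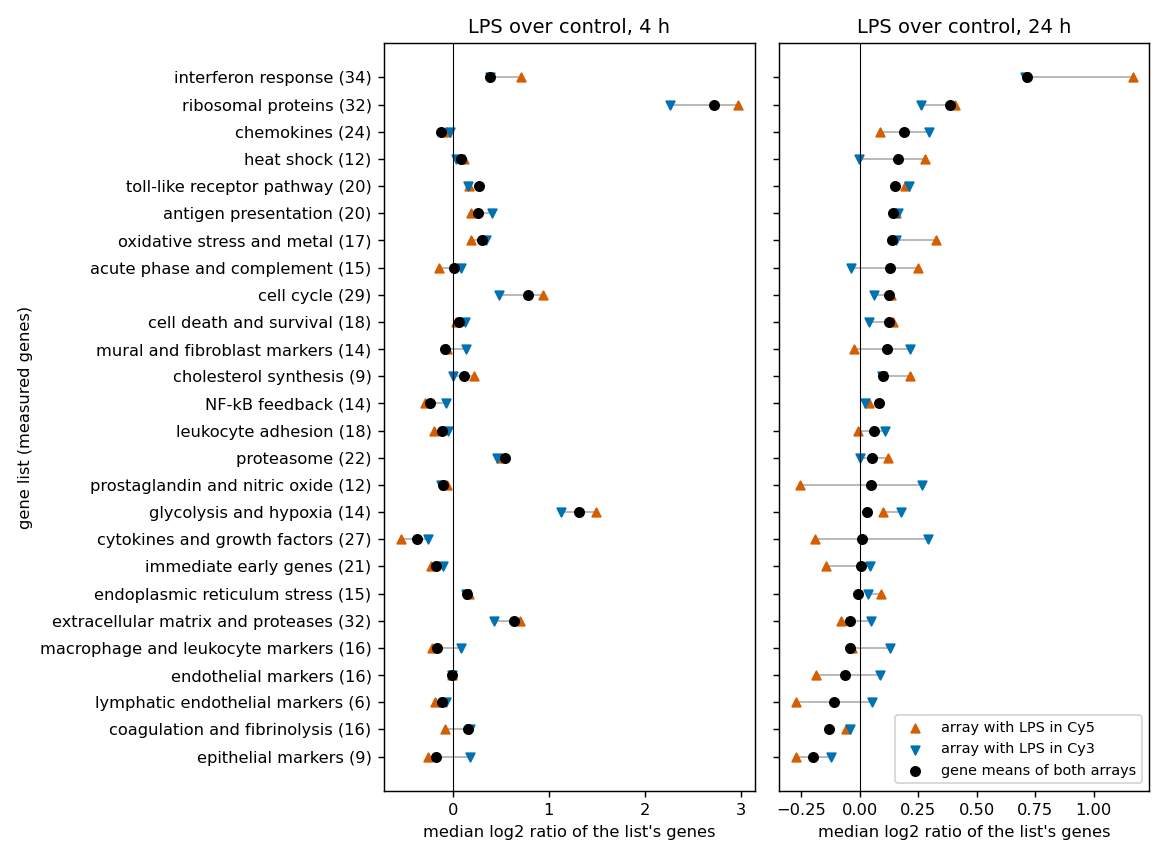
Median log2 ratio of LPS over control (horizontal axes, which differ in range) of the genes of 26 lists at 4 h (left) and 24 h (right), with the number of measured genes in brackets. Triangles are the medians on single arrays and black points the medians of the gene means; the ribosomal protein list lies at 2.72 at 4 h and 0.39 at 24 h, and the interferon list at 0.39 and 0.71.

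Markers of cell types were set beside these groups. The endothelial list had a median of 0.00 at 4 h and -0.06 at 24 h, and Cdh5, VE-cadherin, was its only gene past the rule, at -3.47 ± 2.12 at 4 h, with probes that differed in sign. Lymphatic endothelial markers had medians of -0.11 and -0.11, and none of 6 met the rule. Macrophage and leukocyte markers had medians of -0.16 and -0.04, with Coro1a higher at 24 h (1.05 ± 0.15). Mural and fibroblast markers had medians of -0.08 and 0.12, with 5 of 14 higher and 1, Lum, lower at 4 h; the higher ones included Pdgfra (1.92 ± 1.15), S100a4 (1.75 ± 0.86), Dcn (1.70 ± 0.19) and Acta2 (1.48 ± 0.67), and Pdgfra also at 24 h (1.14 ± 0.54). Epithelial markers had medians of -0.17 and -0.20, with Cldn3 lower at 4 h (-1.66 ± 0.56).

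Compared between the times, 46 genes were higher at both, against 16.3 for independent lists, and 8 were lower at both, against 5.14. The genes higher at 4 h and lower at 24 h numbered 10 (7.77 for independent lists), and those lower and then higher 4 (10.8). Ifi47, Irgm2, Ifih1, Rsad2, Usp18, Ifi35, Stat2, Il33, Saa3, Timp1, Ier3, Ccl7, Casp4 and Fth1 were among those higher at both. Of these, Rsad2, Stat2, Saa3, Ier3 and Ccl7 turned in sign at 4 h with centring on the abundant transcripts. Across genes the ratios of the times correlated at r = 0.16 (Spearman's rho 0.18), and 54.9% had the same sign; the dye parts of the times correlated at 0.15. Whether the control RNA was shared between the times is not known, and part of the overlap may come from shared controls. Part may also come from a trend with abundance at both times. Abundant transcripts outside translation had medians of 1.49 at 4 h and 0.17 at 24 h, the latter at the 98.7th percentile of random lists. Without the unreversed 24 h array the correlation was 0.018.

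By the rule for a difference between the times, 917 genes were higher at 24 h than at 4 h and 1113 lower. Centring on the abundant transcripts gave 6206 and 223, and leaving out the unreversed 24 h array gave 1576 and 1405. The largest differences upward were those of Thoc3 (-3.03 ± 5.39 to 2.58 ± 0.45, with its 4 h arrays at -6.84 and 0.79), Snrnp48 (-3.82 to 1.25), Ttpal (-0.65 to 4.40), 2900016B01Rik (-4.67 to 0.37) and Med26 (-5.02 to -0.12). Downward they were those of Il17rc (6.58 to -0.17), Clec12b (5.74 to -0.04), H3f3b (5.79 to 0.25), Ppia (5.76 to 0.25) and Pabpc1 (5.73 to 0.46). Of 34 interferon genes, 8 were higher at 24 h than at 4 h, among them Gbp2, Ifit3, Ifit2, Igtp, Mx1, Eif2ak2 (4 h oligonucleotides at -0.013 and 0.10) and Irf7, and 4 were lower, among them Ifitm3 (by -3.91) and Ifih1 (by -1.58). Ccl2, Vcam1, Mt2, Timp1 and Saa3 were also higher at 24 h than at 4 h. These differences were not tested, since each time is 1 RNA pair.

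The only test was a limma fit of the response shared by both times, which can pass a gene only where the 2 pair means are alike. It called 0 genes higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.76 and 513 of 11138 genes at an unadjusted p under 0.05. With centring on the abundant transcripts, the limma fit called 0 higher and 8 lower, with a smallest adjusted p of 0.023. Centred on each array's median and adjusted over the list alone, 3 of 34 interferon genes passed, all higher in 4 of 4 arrays. These were Usp18 at a shared log2 ratio of 1.93 ± 0.29 (SE), Irgm2 at 2.20 ± 0.30 and Ifi35 at 1.80 ± 0.27, each at an adjusted p of 0.043 by limma. In the oxidative stress and metal list, Fth1 passed likewise at 2.31 ± 0.27, with an adjusted p of 0.028 by limma. No other of the 26 fixed lists had a gene that passed. Each list was adjusted by itself, with no correction for the number of lists, so some passes by chance are possible. At this threshold chance alone gives a pass in about 1.3 of 26 lists, and only the interferon and the oxidative stress lists had one. The number of lists with a pass is thus near chance. The 513 genes at an unadjusted p under 0.05 in the limma fit were likewise no more than chance gives. Over all genes, each of these genes had an adjusted p of 0.76 by limma. The lists were not adjusted again with centring on the abundant transcripts, which lowers every 4 h value. On simulated data the fit recovered 67% of genes changed 4-fold at both times. Those data held the same change at both times and only the spread within pairs. Differences between the times, which the fit takes as error, were not simulated, so that share does not carry over to these arrays.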

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

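The dye bias tests, the test on the glycolysis list and the test of a mislabelled reversal were chosen after the results they bear on had been seen, as were the added lists and the bootstrap interval of the further interferon genes. Several genes lay on opposite sides of 0 at the times on all 4 arrays, and none of these differences was tested. Some were close to 0 at 1 time, such as Clec12b (-0.04), Atp5b (-0.08) and Zbp1 (-0.11) at 24 h. A small shift in centring would turn such a sign. As 24 h minus 4 h on the log2 scale, higher at 24 h were Snrnp48 (5.08), 2900016B01Rik (5.05), Trafd1 (3.60), Tnip1 (3.36), Vegfa (2.37), Serpinb1a (2.37), Irf7 (1.94), Cd3e (1.62), Sdf2l1 (1.34), Myd88 (1.24) and Cxcl16 (1.16). Lower at 24 h were Clec12b (-5.78), Atp5b (-5.14), Rps7 (-4.79), Ifna9 (-4.72), Zyx (-3.98), Actg2 (-3.93), Timp3 (-3.59), Slc40a1 (-2.60) and Zbp1 (-1.61). The array medians of the NF-kB feedback list and the chemokine list were likewise below 0 at 4 h and above 0 at 24 h, with median differences over their genes of 0.019 and 0.27, also not tested. Of 8104 spots without a single gene symbol, which no comparison used, 765 met the 2-fold rule at 4 h against 531 from dye effect and noise; at 24 h 329 met it, against 362.

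At 4 h the ribosomal protein genes stood high with a list median of 2.72. A dye effect shared by the arrays is taken out of that median by the averaging. The dye part of 0.49 therefore adds little as a test of dye bias. A response limited to translation genes is argued against by the glycolysis list at 1.32, above at least 99.99% of random lists on each array, and by abundant transcripts outside translation at 1.49, though these missed the bound of 1 set beforehand on the reversed array, at 0.78. Unequal labelled RNA or signal in the pair, which moves ratios with abundance, stays open: abundant transcripts lay high, unrelated-tissue transcripts low at -0.23, and the abundant list was at 0.17 at 24 h, the 98.7th percentile of random lists. A broad response of abundant transcripts to LPS may give the same values, and 1 RNA pair without intensities does not separate them.

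At 24 h the interferon list stood at 0.71. Here too the averaging takes out a dye effect shared by the arrays. The dye part of 0.26 and the medians above 0 on both arrays therefore add little as a test of dye bias. A trend with abundance is argued against by the list lying 0.54 above the abundant transcripts (bootstrap 95% interval 0.37 to 1.27). On the single arrays the interferon list lay at 1.17 and 0.71, against 0.30 and 0.07 for the abundant transcripts. Bootstrap intervals here and in the next paragraph can only resample genes, which share the same arrays. They hold no variation between RNA pairs or arrays. An interferon response of LPS-treated cells cannot be told apart from a narrower set of changes: the 36 further interferon-induced genes had a median of 0.064, at the 70.1st percentile of random lists, and its interval of -0.072 to 0.56 holds the bound of 0.18 that the test needed; the median by itself lies under that bound, which without the interval would count against such a response. On the single arrays that list lay at 0.25 and 0.22, at the 99.7th and 98.0th percentile. The interferon pattern may be biological, as a hypothesis only.

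The arrays of 24 h correlated at only 0.10 across genes. For a reversal not made or mislabelled, the interferon list's median on the turned array was 0.71, above all of the random lists drawn. That list was singled out by its mean over both turned arrays, so this value is not independent of the choice. Some other lists lay on opposite sides of 0 on the arrays with LPS in Cy5 and in Cy3, such as the cytokine list at -0.19 and 0.29. A mislabelled reversal is therefore not settled by 1 list. That few genes changed, so that most ratios are dye effect and noise, may account for the low correlation: across 70 interferon genes the arrays correlated at 0.43 (bootstrap 95% interval 0.14 to 0.67), against 0.094 across all others.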

How the results depend on the processing

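The cause of the changes given here was not tested except where the setting itself makes them. No setting run removed the interferon list at 24 h or the ribosomal list at 4 h from above the random range; their medians were 1.06 and 2.12 with quantile normalization. No paired analysis was possible because each time point is 1 RNA pair and the labels carry no replicate numbers. A setting where a single measured array is enough was not run, since no value was missing; values as deposited changed no count by more than 3.

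Counts are given as genes higher, then lower, against 973 and 643 at 4 h, 187 and 89 at 24 h, and 917 and 1113 for the difference. A 1.5-fold threshold gave 346 and 183 at 24 h and 1711 and 1819 for the difference. A 3-fold threshold gave 569 and 306, 73 and 15, and 378 and 585. Dye effect and noise gave 112 calls at 3-fold at 4 h and 79 at 24 h, which at 24 h is close to the number called. Counting each spot by itself, which counts more items, gave 2119 and 1416, 528 and 286, and 2148 and 2552, with 11 lists outside the random range at 4 h against 7. At 24 h, quantile normalization gave 411 and 148, arrays scaled to one spread 142 lower, and the mean alone 388 and 280. Limma on the 4 arrays taken as independent gave 134 and 76 at 4 h and 0 and 0 at 24 h and for the difference (579 and 1326 genes at an unadjusted p under 0.05). With a dye term it gave 0 in each, with 2373, 702 and 1505 genes at an unadjusted p under 0.05. Leaving out each array in turn, where a lone array's dye effect stays in, gave 1376 to 1476 and 996 to 1007 at 4 h, 502 to 771 and 310 to 818 at 24 h, and 923 to 1576 higher for the difference. It gave 0.71 to 1.17 for the interferon list at 24 h, 3 to 4 lists outside the random range at 24 h, and 0.018 to 0.21 for the correlation of the times.

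Centring on abundant transcripts, added after seeing the data, moved every ratio by a constant per array, so signs turn by construction and places among random lists stay. It gave 197 and 6701 at 4 h, 106 and 187 at 24 h, 6206 and 223 for the difference, 8 lower in the shared limma fit, and 1.29 for the ribosomal list. At 4 h it turned the interferon (-1.04), cell cycle (-0.65), matrix (-0.80), glycolysis (-0.11), proteasome (-0.89), further interferon (-1.08), respiratory chain (-0.34) and actin (-0.91) lists, the abundant list itself at 24 h (-0.018), and Saa3 (-0.14), Ier3 (-0.16), Nfkbiz (-0.29), Ccl7 (-0.42), Cxcl12 (-0.13), Ikbkb (-0.17), Gas6 (-0.12), Sod1 (-0.29), Bad (-0.13), Canx (-0.38), Rsad2 (-0.10), Stat2 (-0.29), Ly6e (-0.22), Adar (-0.37) and Ifi211 (-0.37). No other setting turned a called value in sign. Of 394 values of named genes, 99 moved by more than the SD between arrays with quantile normalization, 43 with scaling and 14 with centring on named genes.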

Other observations

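The lists in this part were drawn up after the first results had been seen. Mitochondrial respiratory chain genes had a 4 h median of 1.09, with 12 of 27 measured genes higher and 0 lower, and Cox6a1, a subunit of cytochrome c oxidase, lay at 3.51 ± 1.14 (SD, 2 arrays). At 24 h their median was 0.22, at the 98.5th percentile of random lists, and none met the rule. Actin cytoskeleton and adhesion genes had medians of 0.52 at 4 h, with 10 of 28 higher, and 0.30 at 24 h, at the 99.9th percentile. With centring on the abundant transcripts, which leaves the place among random lists as it was, the 4 h medians of these lists were -0.34 and -0.91. Arpc5, a subunit of the Arp2/3 complex, was higher at both times, at 4.06 ± 0.55 and 1.69 ± 1.19, while the focal adhesion gene Zyx lay at 3.59 ± 1.49 and -0.39 ± 0.32. Of 50 abundant transcripts outside translation, 25 were higher at 4 h, among them Actg1 at 2.66, Vim at 1.90 and Nme2 at 3.51, and at 24 h only Nme2 met the rule, at 1.09, with the list median at the 98.7th percentile. Of 57 transcripts of unrelated tissues, 1 was higher at 4 h, Ins2 at 1.73 with probes that differed in sign, and 3 were lower.

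Of 36 further interferon-induced genes, 5 were higher at 4 h, with a list median of 0.35: Cmpk2 at 1.81 ± 0.27, Zbp1 at 1.51 ± 0.21, Ly6e at 1.21 ± 0.29, Ifi211 at 1.06 ± 0.09 and Adar at 1.06 ± 0.17. With centring on the abundant transcripts, the 4 h median was -1.08, and Ly6e (-0.22), Adar (-0.37) and Ifi211 (-0.37) turned in sign. At 24 h Cmpk2, a mitochondrial nucleotide kinase, was the only 1 of these 36 past the rule, at 1.46 ± 0.17, and 2 met it when the reversed array was turned back. In the iron and metallothionein list, Fth1 and the iron exporter gene Slc40a1 (1.77) were higher and Ftl1 lower at 4 h, and Mt2 and Fth1 were higher at 24 h, with list medians of 0.04 and 0.08 over 14 genes. Among 13 serum amyloid and secreted inhibitor genes, Timp1 and Saa3 were higher at both times, Timp3 was higher and Serpinb1a lower (-1.53) at 4 h, and the list medians were 0.08 and 0.18.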
